A study of Canis lupus familiaris with 32 samples.

How the data were processed

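RNA sequencing of hip soft tissues of dogs was analysed from the tables the authors deposited. The hip joint capsule is the fibrous sleeve around the joint, and the teres ligament runs inside the joint from the femoral head to the acetabulum. Per the labels, 32 libraries came from 25 dogs, and each library was a separate tissue sample. Total RNA was isolated with Trizol, ribosomal RNA was subtracted and strand-specific libraries were built, per the labels' protocols. The 7 groups were capsule and ligament of dogs affected by hip dysplasia, of adult control dogs and of young dogs under 1 month of age, and the hip of embryos. Replicates of a group came from different dogs by the dog identifiers in the labels, and 7 dogs gave both a capsule and a ligament library.

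Per the submitters' processing notes, cutadapt 1.8, Bowtie2 2.2, TopHat2 2.0.13 and Cuffdiff 2.2.1 were used with the canFam3 genome. The roles of the tools, the gene annotation release and the strand setting of the counting are not given in the sources used here. The deposited tables list, per gene and library, an estimated count of fragments before scaling, per the file headers. The deposited estimated counts were whole numbers except for 0.332% of values (more than 1e-06 off a whole number), and they were rounded to whole numbers before testing. The authors also deposited a scaled fragment signal, which is the estimated count divided by 1 factor per library, and FPKM values on that scale. FPKM was used in an alternative test, and the ratio of scaled signal to FPKM gave each gene's relative length. The table of all samples was used throughout. Fragment values in the separate capsule and ligament tables differed from it at 0 values. Of all values in that table, 9 (in 3 genes) carried the status FAIL, and their fragment counts were kept.

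Genes are listed by Ensembl gene ID only, 24580 in all. The reference table used for names pairs none of these IDs with a symbol (0 matched), so the files used here do not pair the IDs with gene names. The gene lists fixed before the data were examined (matrix, cartilage, tendon, muscle, immune and other markers, named by symbol) therefore could not be tested. The rule for named genes also asked for a symbol. It was applied without that condition and held to 2 genes in each direction. These were the genes with the largest log2 fold change among those with an adjusted p under 0.05, a mean of at least 5 CPM (fragment counts relative to the library total) in the higher group, and no overlap between the groups, or the same sign in every dog of the paired comparison. IDs of near-identical gene copies could not be recognised without names, and fragments shared between such copies or overlapping genes remain an uncertainty for each named ID.

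Each comparison was tested with edgeR 4.0.16 in R 4.3.3 on the rounded counts of the groups compared. Genes were kept with filterByExpr, libraries were scaled with TMM, and the robust quasi-likelihood F test was used with Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Log2 fold changes are given with standard errors derived from the F statistic, and CPM values use TMM-scaled library sizes. Capsule and ligament were compared within the 7 dogs that gave both, with the dog as a block. Differences between tissues in the disease and age effects were tested as interaction terms, in which libraries were treated as independent although some dogs gave both tissues. A fold against a group with 0 fragments is a lower bound, taken against a floor of 3 fragments over the whole group. With 1 to 3 fragments in the lower group, the ratio of pooled fragments is given with its exact 95% binomial interval (confidence 0.95). Intervals and floors cover counting error only, since the libraries have no molecular identifiers.

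Genes called in a comparison were followed as a group into another comparison that shared no library with it. The groups were tested with limma 3.58.1 camera on log2 CPM (prior count of 2), with a preset correlation of 0.01 and again with an estimated correlation, and p-values were adjusted over all gene group tests. These tests were chosen after the first counts of calls had been seen. An age index was computed for each library as the mean log2 CPM of genes called higher in young dogs minus that of genes called lower, scaled to 0 at the mean of the controls and 1 at the mean of the young libraries of the tissue. The genes of the index were those called in the other tissue. Group differences in single values were tested with two-sided exact permutation tests, adjusted by the Benjamini-Hochberg method within each family.

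Total fragments per library ran from 2857235 to 9895143 (median 4993068). No pair of libraries within a group agreed to within sampling noise, the lowest chi-square per gene among 64 pairs being 4.24, where counting noise alone gives about 1. The tests were tested on simulated data before use, with negative binomial counts drawn from the real means, library sizes and dispersions. In these, 200 genes were changed, all with an average log2 CPM above 1, and genes were drawn independently. Recovery of weakly expressed genes was therefore not measured. Of 100 genes changed 4-fold, 87 were recovered in the simulated affected capsule comparison (12718 genes), 75 in the affected ligament comparison (12937 genes) and 87 in the adult affected ligament comparison (12505 genes). Of 100 genes changed 2-fold, 11, 9 and 19 were recovered in these comparisons. Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, limma-trend on log2(FPKM + 1), each library left out in turn, all libraries of a tissue in 1 fit, the table of 1 tissue alone, age class as a covariate, fits with or without blocks, and limma voom with library quality weights. In the comparisons of 2 groups, equal replicate numbers belong to different dogs by the labels, so numbers were not used to pair samples. Summaries and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.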

Results

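Gene expression was measured by ribosomal RNA-depleted, strand-specific sequencing in hip joint capsule and teres ligament of dogs, a natural model of developmental dysplasia of the hip. Affected capsules came from 4 dogs (1 adult and 3 aged 4 months) and control capsules from 5 adults. Affected ligaments came from 7 dogs (4 adults and 3 aged 4 months) and control ligaments from 3 adults. Young dogs under 1 month gave 6 capsules and 4 ligaments, and 3 libraries came from whole embryonic hip. Library totals lay between 2857235 and 9895143 fragments. The 10 most abundant genes held 27.3% ± 2.48 (SD, n = 4) of fragments in affected capsules and 21.1% ± 2.45 (n = 5) in control capsules (exact permutation p = 0.0238, adjusted over 6 tests 0.0429). They held 12.3% ± 0.426 (n = 3) in embryonic hip, against 27.7% ± 4.42 (n = 6) in young capsules (exact permutation p = 0.0119, adjusted 0.039).

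**Figure D1:**
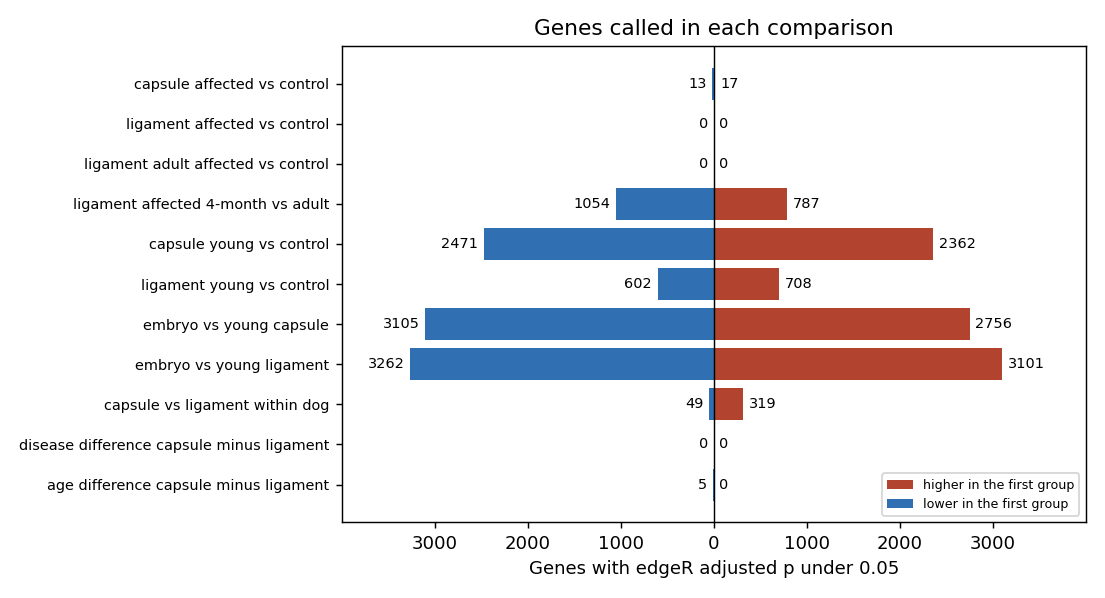
Genes called by edgeR at an adjusted p under 0.05 in each comparison. Bars to the right count genes higher in the first group named and bars to the left genes lower in it, on a linear axis of gene counts; the interaction terms count genes whose effect was higher or lower in capsule. The embryo comparisons called 5861 and 6363 genes, and the 2 comparisons of affected with control ligaments called 0.

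The case and control comparison in capsule asked which genes differ in dysplastic hips. In affected capsules, 30 of 12718 genes were called, 17 higher and 13 lower. ENSCAFG00000011534 was 18.8-fold higher, at 168 ± 100 CPM (SD, n = 4) in affected against 8.95 ± 4.73 CPM (n = 5) in control capsules (log2 fold change 4.23, SE 0.65, edgeR adjusted p = 0.039). ENSCAFG00000000681 was 11.5-fold higher, at 29.9 ± 20.5 CPM against 2.6 ± 0.866 CPM (log2 3.52, SE 0.47, adjusted p = 0.013). ENSCAFG00000017302 fell from 19.5 ± 11.7 CPM in controls to 0.238 ± 0.284 CPM in affected capsules (log2 -6.06, SE 0.68, adjusted p = 0.0063). ENSCAFG00000020059 fell from 9.7 ± 6.93 to 0.301 ± 0.336 CPM (log2 -5, SE 0.81, adjusted p = 0.039). All controls were adult. With age class as a covariate, where the disease term rests on the 1 adult affected library against 5 controls, 11 genes were called, 5 of them among the 30. In that fit the spread comes from the controls and the dogs aged 4 months. ENSCAFG00000000681 had a log2 change of 3.86 (SE 0.61). The other 3 named genes kept their direction with larger standard errors and were not called. ENSCAFG00000011534 stood at log2 4.95 (SE 0.79) and ENSCAFG00000020059 at -3.59 (SE 1.3, on 3 fragments in the adult affected library). ENSCAFG00000017302 had 0 fragments in that library, so the size of its change was not measured. Leaving out 1 library at a time gave 2 to 41 genes (10, 4 and 4 without affected replicates 2, 3 and 4, and 2, 18, 7, 11 and 7 without control replicates 1 to 5), while DESeq2 called 141. With 1 library left out, ENSCAFG00000017302 stayed called; ENSCAFG00000000681 was lost without control replicate 1 (edgeR adjusted p = 0.053), ENSCAFG00000011534 without affected replicates 1, 3 or 4 or control replicates 1, 2, 4 or 5 (0.054 to 0.11), and ENSCAFG00000020059 without affected replicates 2, 3 or 4 or control replicates 1, 3 or 4 (0.066 to 0.12). The log2 fold change of ENSCAFG00000017302 was -6.78 without affected replicate 2, and that of ENSCAFG00000020059 was -5.89 without affected replicate 1.

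**Figure D2:**
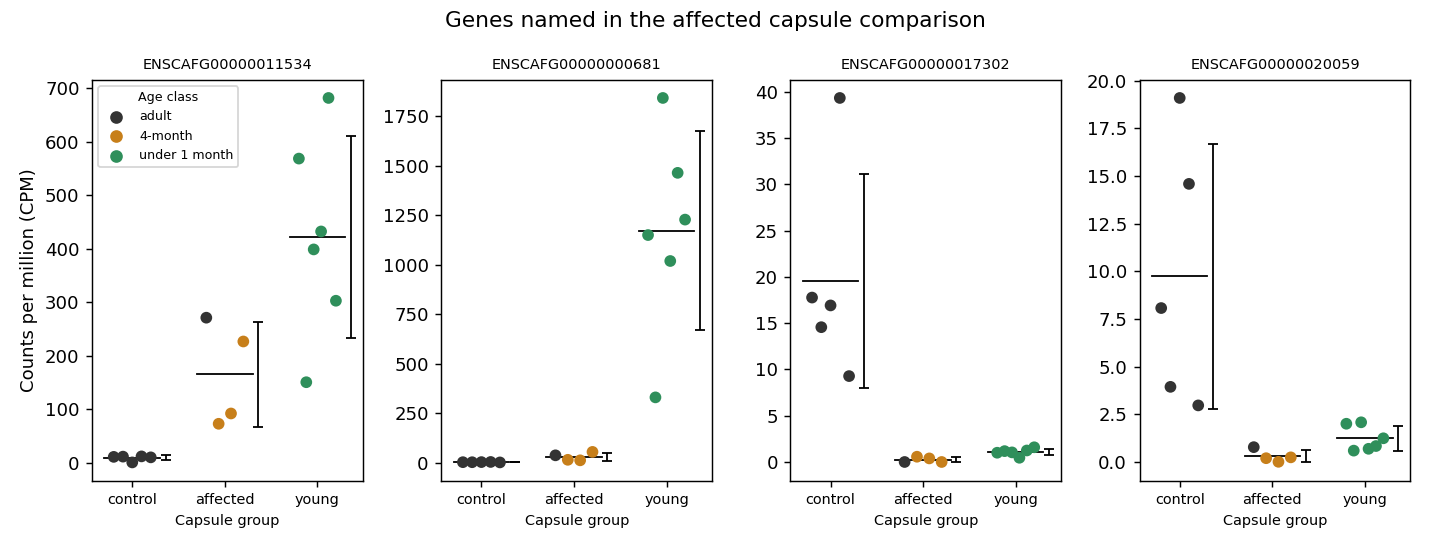
CPM of the 4 genes named for affected capsules, 1 point per library, on linear axes that differ between panels, with TMM scaling over all 32 libraries. Horizontal lines are group means and bars are 1 SD (n = 5 control, 4 affected and 6 young capsules). For ENSCAFG00000011534 the affected mean of 166 CPM lay between the control mean of 8.99 and the young mean of 423.

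The genes that set young ligaments apart from adult ones moved as a group in affected capsules. Of 607 genes higher in young than in control ligaments, 549 (90.4%) had a positive fold change in affected capsules, with a median log2 change of 0.548. Of 592 genes lower in young ligaments, 462 (78%) had a negative change there, with a median of -0.257. Both shifts passed with an estimated correlation (camera adjusted p = 0.0068 for the higher and 0.022 for the lower genes). Of the 17 genes called higher in affected capsules, 16 were also called higher in young ligaments, where independent lists would share 0.842, and 6 of the 13 lower genes were called lower there, against 0.628. ENSCAFG00000000681 was among the shared genes. These comparisons share no library, but 1 control dog gave a library to each. Without its capsule (control replicate 3), 523 of 596 higher genes (87.8%) and 434 of 584 lower genes (74.3%) kept those directions. The camera adjusted p was 0.0096 and 0.053 with an estimated correlation. That capsule fit called 2 higher and 5 lower genes, of which 2 and 1 were called alike in young ligaments (0.0984 and 0.241 expected).

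On the age index, which runs from 0 at the control mean to 1 at the young mean, affected capsules averaged 0.35 against 0 in controls (exact permutation p = 0.00794, the smallest possible, adjusted over 5 tests 0.0397). All 4 affected capsules lay above all 5 controls. The 3 capsules of dogs aged 4 months averaged 0.353 ± 0.0827 (SD, n = 3), and the capsule of the adult affected dog stood at 0.339. Controls had an SD of 0.0931 (n = 5) and reached at most 0.0838. Ligaments of adult affected dogs averaged -0.195 ± 0.183 (n = 4) against 0 ± 0.254 (n = 3) in control ligaments, a difference smaller than the spread between control libraries (exact permutation p = 0.314, adjusted 0.392). This difference of -0.195 was -0.341 without control replicate 3 (exact permutation p = 0.133), -0.108 without control replicate 1 and -0.121 without affected replicate 1 (0.6 each). Affected ligaments at 4 months averaged 0.309 ± 0.178 (n = 3), higher than those of affected adults (exact permutation p = 0.0286, the smallest possible, adjusted 0.0477).

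**Figure D3:**
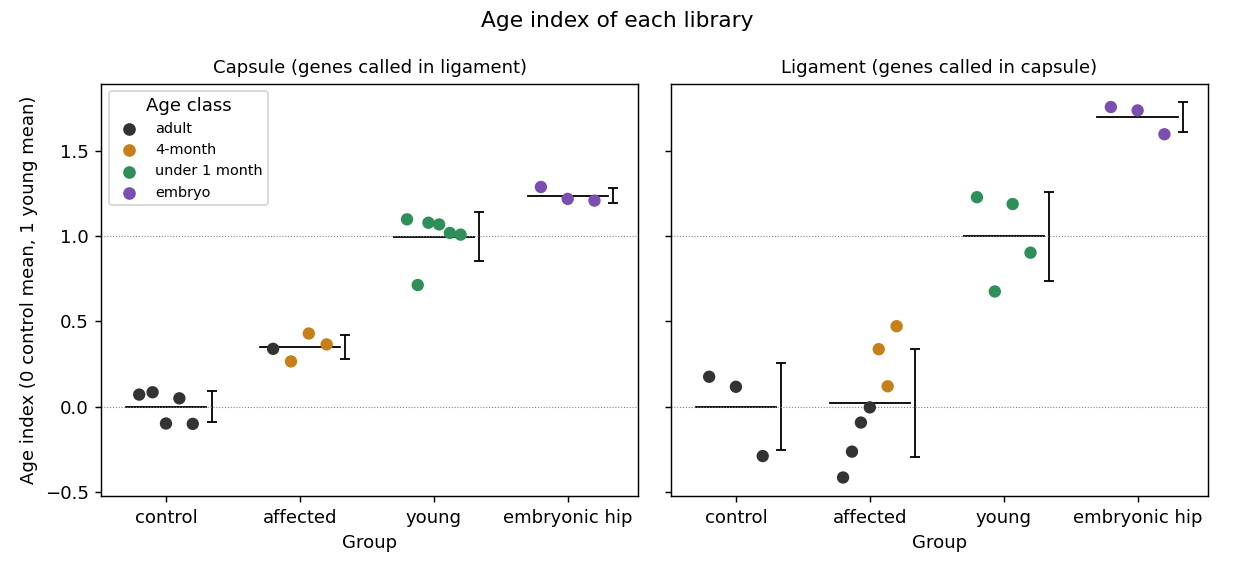
Age index of each library (unitless, linear axis), computed in capsule from genes called between young and control ligaments and in ligament from genes called in capsule. Points are libraries coloured by age class, horizontal lines are group means and bars are 1 SD. The 4 affected capsules lie between 0.265 and 0.429, above the controls, whose highest is 0.0838.

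In ligament, the case and control comparison gave no called gene. Across 7 affected and 3 control ligaments, 0 of 12937 genes passed with edgeR, 1058 had an unadjusted p under 0.05, and DESeq2 called 10. Between the 4 adult affected and the 3 adult control ligaments, the comparison at matched age class, 0 of 12505 genes passed, 2374 had an unadjusted p under 0.05, and DESeq2 called 68. Without control replicate 3, edgeR called 1850 genes, 1077 higher and 773 lower in adult affected ligaments, and each other library left out gave 0. Fits that keep this library also gave calls. Voom with library quality weights, which can give less weight to an outlying library, called 738 (532 higher, 206 lower), 722 of them among the 1850. With the replicate number as a block, which leaves out affected replicate 4, 204 were called (141 higher, 63 lower), 138 among the 1850. Of the 68 genes of DESeq2, 65 were among the 1850. These fits use the same libraries, so the overlaps are no independent support. The genes called in affected capsules had fold changes of the same sign in adult affected ligaments, positive for 16 of the 16 higher genes tested and negative for 12 of the 12 lower ones (medians 1.11 and -0.934 on the log2 scale). Without the ligament of the dog that gave both controls (control replicate 1), the counts were again 16 of 16 and 12 of 12. As a group, neither set passed with an estimated correlation (camera adjusted p = 0.14 and 0.23). The interaction term for a difference of the disease effect between capsule and ligament called 0 genes with edgeR (290 at an unadjusted p under 0.05) and 0 with DESeq2. In simulated data this term recovered 44 of 100 genes changed 4-fold and 2 of 100 changed 2-fold, so 0 calls do not show equal effects.

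Within affected ligaments, dogs aged 4 months were compared with adults. Of 12619 genes, 787 were higher and 1054 lower at 4 months. In the labels, the identifiers of the 3 dogs aged 4 months share a beginning that no adult affected dog has. What it stands for is not given, so it and age cannot be told apart here. ENSCAFG00000024944 averaged 12.8 ± 8.97 CPM (SD, n = 3) at 4 months and 0.354 ± 0.477 CPM (n = 4) in adults (log2 4.8, SE 0.87, edgeR adjusted p = 0.012). ENSCAFG00000001917 had 72 fragments over the libraries at 4 months and 0 in adults, at least 31.1-fold higher (edgeR adjusted p = 0.01). ENSCAFG00000016150 was lower, at 8.35 ± 2.86 against 179 ± 70.4 CPM (log2 -4.42, SE 0.4, adjusted p = 0.0034), as was ENSCAFG00000004443, at 4.91 ± 3.22 against 227 ± 195 CPM (log2 -5.5, SE 0.9, adjusted p = 0.013). The log2 change of ENSCAFG00000024944 was 6.01 without affected replicate 4, and that of ENSCAFG00000004443 was -6.13 and -4.74 without replicates 7 and 1. The bound of ENSCAFG00000001917 fell to 18.8-fold without replicate 7 and 20.5-fold without replicate 4. Of the genes higher at 4 months, 572 of 771 (74.2%) had a positive fold change in young against control capsules. Of the genes lower at 4 months, 898 of 1040 (86.3%) had a negative one there. Both called lists overlapped in the same direction at 308 higher genes (139 expected of independent lists) and 576 lower genes (210 expected). Set against all other genes, the shift of these groups in capsule did not pass with an estimated correlation (camera adjusted p = 0.27 and 0.14). Leaving out 1 library gave 549 (without affected replicate 6) to 2203 genes, and 845, 803 and 826 without replicates 7, 2 and 3.

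The age comparison set young dogs under 1 month against adult controls. In capsule, 2362 of 12589 genes were higher and 2471 lower in young dogs, 1052 and 1164 of them by at least 2-fold. ENSCAFG00000018264 averaged 45.6 ± 19.8 CPM (SD, n = 6) in young capsules and had 1 fragment over the 5 controls, a ratio of 1020 (95% counting interval 183 to 40400, edgeR adjusted p = 1e-06). ENSCAFG00000017925 had 3290 fragments over the young capsules against 1 in controls, a ratio of 2420 (435 to 95700, adjusted p = 0.00075), which was 1170 without young replicate 5. Without control replicate 5, which held the single fragment of each of these 2 genes, they were at least 263-fold and 623-fold higher. ENSCAFG00000005854 fell from 46.8 ± 38 CPM in controls to 0.571 ± 0.351 CPM in young capsules (log2 -6.29, SE 0.76, adjusted p = 0.00012), and ENSCAFG00000015054 from 185 ± 242 to 1.73 ± 1.45 CPM (log2 -6.73, SE 1.2, adjusted p = 0.0016; log2 -5.58 without control replicate 3).

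In ligament, 708 of 12701 genes were higher and 602 lower in young dogs. ENSCAFG00000000681 averaged 995 ± 246 CPM (SD, n = 4) in young and 1.54 ± 2.2 CPM (n = 3) in control ligaments (log2 9.37, SE 0.87, edgeR adjusted p = 0.0011). Without control replicate 1 the controls held 3 fragments (ratio 3690, 1260 to 17900), and without control replicate 2 the log2 change was 8.78. ENSCAFG00000018264 was higher in this tissue too, at 11.5 ± 5.03 CPM against 0 fragments, at least 61.4-fold (adjusted p = 0.0022; at least 37.6-fold without control replicate 2). ENSCAFG00000014924 averaged 12.1 ± 13.9 CPM in young against 1340 ± 663 CPM in control ligaments (log2 -6.76, SE 0.85, adjusted p = 0.003; log2 -8.01 without young replicate 2). ENSCAFG00000013931 had 3 fragments in young and 146 in control ligaments, a ratio of 77.1 (25.9 to 378, adjusted p = 0.0031), which was 155 without young replicate 2 and 39.7 without control replicate 2. DESeq2 called 2040 genes, and leaving out 1 library gave 617 (without young replicate 3) to 1774, with 783, 848 and 790 without young replicates 1 and 4 and control replicate 2.

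The young and adult differences ran in parallel in the tissues. Genes called in ligament were compared with capsules of dogs that gave no ligament, so that no dog entered both sides. Of 677 genes higher in young ligaments, 653 (96.5%) had a positive fold change in young capsules, with a median log2 change of 1.52. Of 582 lower genes, 557 (95.7%) had a negative one, with a median of -1.04 (camera adjusted p = 0.0096 and 0.0068 with an estimated correlation). Called lists shared 505 higher genes, with 102 expected, and 346 lower genes, with 87.1 expected, while 1 gene was higher in ligament and lower in capsule. Fold changes correlated at Pearson r = 0.703 and Spearman rho = 0.557 across 12283 genes, which are not independent replicates. Both fold changes fell with relative gene length (Spearman rho = -0.147 in ligament and -0.226 in capsule), and with length held fixed the rho between the tissues was 0.544. The interaction term called 5 genes with edgeR, all with a lower young effect in capsule. ENSCAFG00000015412 averaged 10.5 ± 5.45 CPM (SD, n = 6) in young and 24 ± 9.2 CPM (n = 5) in control capsules, but 19.6 ± 2.64 CPM (n = 4) in young and 4.42 ± 1.79 CPM (n = 3) in control ligaments (interaction log2 -3.34, SE 0.55, adjusted p = 0.035). ENSCAFG00000005688 averaged 8.33 ± 2.67 and 14.6 ± 4.8 CPM in young and control capsules, but 18.5 ± 6.3 and 5.11 ± 1.42 CPM in ligaments (log2 -2.67, SE 0.47, adjusted p = 0.048). DESeq2 called 106 genes by the interaction term, and leaving out 1 library gave 0 to 715. The count was 715 without ligament control replicate 3, 2 without capsule control replicate 5 or ligament control replicate 1, and 0 without capsule control replicates 1, 3 or 4, capsule young replicates 1, 5 or 6, ligament control replicate 2 or ligament young replicates 2, 3 or 4.

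Embryonic hip was set against young tissue to follow age before and after birth, although the embryonic sample was whole hip, so that age and tissue differed together. Against young capsules, 2756 of 13585 genes were higher and 3105 lower in embryos. ENSCAFG00000031641 averaged 80 ± 19.9 CPM (SD, n = 3) in embryonic hip and had 1 fragment over 6 young capsules, a ratio of 2360 (422 to 93100, edgeR adjusted p = 4.4e-09); without young replicate 3, which held it, the gene was at least 684-fold higher. ENSCAFG00000014218 had 728 fragments in embryonic hip and 0 in young capsules, at least 326-fold higher (adjusted p = 0.011), or at least 159-fold without embryo replicate 3. ENSCAFG00000013694 had 0 fragments in embryonic hip and 1277 in young capsules, at least 317-fold lower (adjusted p = 0.026), and ENSCAFG00000011103 averaged 1.28 ± 0.262 CPM against 844 ± 939 CPM (log2 -9.34, SE 1.7, adjusted p = 0.0025; log2 -8.66 without young replicate 2). The call of ENSCAFG00000013694 was lost when any embryonic library was left out (adjusted p = 0.058 to 0.064 in edgeR), with bounds of 205-fold to 220-fold.

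Against young ligaments, 3101 of 13462 genes were higher and 3262 lower in embryonic hip. ENSCAFG00000007233 had 4866 fragments in embryonic hip, at 231 ± 60.2 CPM (SD, n = 3), and 0 in young ligaments, at least 1870-fold higher (edgeR adjusted p = 1e-06). ENSCAFG00000023647 had 3821 fragments, at 182 ± 29.9 CPM, against 0, at least 1470-fold higher (adjusted p = 3.5e-07); without young replicate 2 these bounds were 1250-fold and 980-fold. ENSCAFG00000031939 had 0 fragments in embryonic hip and averaged 9.41 ± 1.16 CPM (n = 4) in young ligaments, at least 66.8-fold lower in embryos (adjusted p = 1.2e-05; at least 43.2-fold to 46.4-fold with 1 embryo library left out). ENSCAFG00000017550 averaged 2.32 ± 1.51 against 961 ± 377 CPM (log2 -8.71, SE 0.53, adjusted p = 2.8e-06; log2 -9.36 without embryo replicate 1). Of the genes higher in embryonic hip than in young ligament, 1770 of 2458 (72%) had a positive fold change in young against adult capsules. Of those lower in embryos, 2077 of 3238 (64.1%) had a negative one there (camera adjusted p = 0.022 and 0.042 with an estimated correlation). These comparisons share no library, and 3 young dogs gave a library to each.

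Capsule and ligament of the same dog were compared in 7 dogs. Of 12593 genes, 319 were higher and 49 lower in capsule. The count of lower genes depended on single dogs: it was 20 and 122 without the dogs of affected capsule replicates 2 and 3, and 21, 26 and 26 without those of young capsule replicates 1, 2 and 6, while 231 to 375 genes were higher with any 1 dog left out. ENSCAFG00000008524 averaged 1270 ± 1120 CPM (SD, n = 7) in capsule and 0.343 ± 0.192 CPM (n = 7) in ligament (log2 11.7, SE 0.48, edgeR adjusted p = 7.9e-08). ENSCAFG00000017522 averaged 898 ± 1470 CPM in capsule and 0.285 ± 0.358 CPM in ligament (log2 11.3, SE 0.63, adjusted p = 7.8e-07; log2 10.3 without the dog of young replicate 1). ENSCAFG00000020033 was lower in capsule, at 0.665 ± 1.09 against 19 ± 22 CPM (log2 -4.55, SE 0.82, adjusted p = 0.012), as was ENSCAFG00000017865, at 2.44 ± 2.53 against 19.4 ± 14.5 CPM (log2 -3.03, SE 0.42, adjusted p = 0.0014). The call of ENSCAFG00000020033 was lost when the dog of young replicate 1 was left out (edgeR adjusted p = 0.055), and its log2 change was -5.17 and -5.51 without the dogs of affected capsule replicates 2 and 3 and -3.88 without the control dog. The fits to dogs of each age class alone share no dog. Of 278 genes called higher in capsule in the 3 young dogs alone, 247 (88.8%) had a positive fold change in the 3 affected dogs aged 4 months. Of these, 99 were called in both, with 3.36 expected. Of 165 genes called lower in capsule in the young dogs, 83 (50.3%) had a negative fold change at 4 months. The 4-month dogs alone gave 159 called genes.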

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

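The tests of a mislabelled control ligament, of an age difference among control ligaments, of depth and of an older animal for the young dog, of the age of the affected dogs, of a few genes taking most of the counts and of tissue labels swapped within dogs were chosen only after a result was seen; the other tests of explanations and the counts over other splits of the samples were set out before their results.

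In 47 sets of 4 to 10 libraries examined for a library far from the rest, 8 held one, where chance gives about 2.35. Capsule control replicate 4 had 25.3% of its fragments in its 10 most abundant genes, against 18.7% to 20.6% in the other 4 controls. Ligament young replicate 2 had 9895143 fragments, against 6018741 to 6538359 in the others. Capsule young replicate 2 had an age index of 0.714, against 1.01 to 1.1 in the other 5. ENSCAFG00000011534 stood at 0.597 CPM in capsule control replicate 3, against 10.1 to 11.9 CPM in the other controls. ENSCAFG00000000681 stood at 657 CPM in ligament young replicate 2, against 1134 to 1226 CPM in the others. The remaining 3 cases were single fragments among libraries with 0: ENSCAFG00000017925 and ENSCAFG00000018264 in capsule control replicate 5 (0.197 CPM each) and ENSCAFG00000031641 in capsule young replicate 3 (0.259 CPM).

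The effect of young age differed between capsule and ligament at 5 genes by the interaction term, all with a lower young effect in capsule. Of 100 groupings with tissue labels permuted within each age, 4 gave as many genes, the real one included. Few groupings reached this count, but it fell to 0 with several single libraries left out, so chance is not firmly excluded. These groupings ignore that 4 dogs gave both tissues; with labels swapped within those dogs and permuted among the rest, 2 of 100 gave as many (highest other 131). In the first set, the highest of the other groupings gave 1276 genes, which points to a structure of the samples other than tissue.

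Affected capsules differed from adult control capsules at 30 genes, and 3 of the 4 affected dogs were aged 4 months. Among 100 splits of the 9 libraries, 3 gave as many genes, the real one included. So many calls were uncommon among the splits, but chance is not firmly excluded. The highest other split gave 97 genes, which points to a structure of the samples beyond disease status. The 10 most abundant genes held at most 30.4% of fragments in an affected and at least 18.7% in a control capsule, which could shift the other genes by 0.224 (log2), while the smallest change among the 30 was 1.26 (0.812 less 2 SE). This argues against a few genes taking most of the counts. At 41 genes called without the adult affected capsule, that library lay beyond all 5 controls in the called direction for 70.7% (95% interval 54.5 to 83.9), against 21% of all tested genes, with a median shift of 1.32 against 2.28 on the log2 scale in the dogs aged 4 months. The share does not decide whether age at sampling is the only cause. The 41 genes were chosen against the same 5 controls, so a further library may lie beyond them more often than at all tested genes. The interval also reaches below the bound of 60 percent, and 1 library carries the test. In the labels, the identifiers of the 3 dogs aged 4 months share a beginning that no control capsule and not the adult affected capsule has. What it stands for is not given. Age, disease and this beginning therefore cannot be told apart here, and a young-like state of affected capsules remains a hypothesis.

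Adult affected and control ligaments differed at 0 genes with all libraries in edgeR and at 1850 without control replicate 3, although weights for library quality gave 738 with this library kept. At those genes, on an index with 0 at the mean of the other controls and 1 at the mean of adult affected ligaments, control replicate 3 stood at 0.849, within the range of the adult affected libraries (0.826 to 1.13). These genes were chosen with that library left out, and capsule controls stood as high as 0.961 and the 3 affected ligaments at 4 months only at 0.26 to 0.399, so the index does not follow disease alone and does not decide whether this is a mislabelled or undiagnosed affected ligament. An age difference among the adult controls may account for it: control replicate 3 had an age index of -0.291, below 0.175 and 0.116 in the other controls but within the adult affected ligaments (-0.417 to -0.00501). The capsule of the dog that gave control replicate 1 stood at 0.375 on the index of the 1850 genes, below 0.667 to 0.961 in the other capsule controls. These genes were called with that dog's own ligament among the controls, so its low capsule value may come from the shared dog and is no support for age. A gene length trend is argued against by a Spearman correlation of 0.0289 between fold change and relative gene length across genes. In the labels, the other control ligaments came from dogs identified by names, while control replicate 3 and the adult affected dogs have codes with digits. Among capsule controls, only the dog at 0.375 has a name, and its ligament entered the choice of the genes. The affected dogs aged 4 months have codes too, but stood at 0.26 to 0.399. What the form stands for is not given, so it cannot be told apart from disease or age here. Disease, age among adult dogs and what this form stands for remain open. Without exact ages, the label adult does not separate disease from age.

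Both libraries of 1 young dog lay toward the adults: with genes called without this dog, its ligament had an age index of 0.58 against 0.809 to 1.12 in the other young ligaments, and its capsule 0.641 against 0.943 to 1.05. Thinned to the depth of the shallowest other young library, they stood at 0.58 and 0.642, which argues against depth, although the ligament was the deepest library. This test replaced an earlier one on rank correlation with the other young ligaments, whose values are not given here. Genes higher in capsule in the other dogs were raised in its ligament by a median of 0.381 (log2), outside the other young ligaments (-0.176 to -0.0745) but far below the 3.46 between young capsules and ligaments. A small share of capsule tissue in the ligament sample stays open, but it would leave the capsule library of the dog unexplained, which argues against it as the cause of both. An older animal within the young class stays open: on an index of genes between embryo and young (1839 higher and 1671 lower in embryos for ligament), its ligament stood at 0.0321, within the other young ligaments (-0.0211 to 0.0378), and its capsule at 0.132, nearer to the embryo than the other young capsules (highest 0.119). Both go against an older animal, but the index left out genes called between young and adult, adult control capsules fell within the young range (mean -0.101), and adult control ligaments (mean -0.0317) lay beyond it by less than the range is wide, so it could hardly have shown age. In the labels, the identifier of this dog has the form of those of the 3 affected dogs aged 4 months and not of the other young dogs; what the form stands for is not given.

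The remaining counts were set against other splits of the same libraries. The real grouping gave more genes than any other split for affected ligaments at 4 months against adults (1841 genes, 636 in the highest of the other splits, 1 of 35 splits as large), young capsules (4833, highest other 3858, 1 of 100) and young ligaments (1310, highest other 13, 1 of 35). It also did so for embryonic hip against young capsules (5861, highest other 14, 1 of 84) and against young ligaments (6363, highest other 6, 1 of 35), and capsule against ligament within dog (368, highest other 2, 1 of 64). In each of these the share was the smallest that the number of splits allows, and shares were not adjusted over comparisons. Such counts were therefore uncommon among the splits, but chance is not firmly excluded, least of all with 35 splits. For the counts of 0 such splits say nothing about chance, since each gives at least 0: all 100 splits of affected and control ligaments (highest other 51), all 35 of adult affected and control ligaments (highest other 1) and all 100 for the disease difference between tissues (highest other 134) gave as many.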

How the results depend on the processing

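The fit by voom with library quality weights was chosen after seeing the data; all other alternatives were listed before the data were examined. The embryo comparisons, young capsules and the disease difference between tissues stayed within 1.5 times their counts under every alternative run. Named genes kept their direction in all 454 alternatives and passed the threshold in 401, with 20 of 30 named results tested in all of their alternatives and past it in each. A further 6 alternatives left 2 of the 30 untested. Apart from the interaction genes, named genes were chosen without overlap or with the same sign in every dog, which nearly fixed their direction. The gene lists fixed beforehand could not be tested, since no ID matched a symbol. Causes of the changes below were not tested unless stated.

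With DESeq2, counts moved to 141 in affected capsules (from 30), 10 in affected ligaments (from 0), 68 in adult affected ligaments (from 0), 2040 in young ligaments (from 1310), 598 between tissues within dog (from 368) and 106 for the age difference between tissues (from 5). Affected capsules gave 47 genes without the low-count filter, 72 with all capsule libraries in 1 fit, 11 with age class as a covariate (5 of them among the 30; 1 adult affected library carries that fit) and 15 with limma-trend on FPKM, where 6 were higher and 9 lower against 17 and 13 in counts. The age difference gave 14 genes with limma-trend on FPKM, 8 higher and 6 lower, against 0 and 5. Quality weights gave 738 genes in adult affected ligaments, against 28 in affected capsules and 0 in all affected ligaments. Capsule against ligament gave 159 genes in the dogs aged 4 months alone (fewer libraries) and 824 over all capsule and ligament libraries without the dog as a block, with 541 higher and 283 lower against 319 and 49; dropping the block alone gave 250 (231 and 19).

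Leaving out each library in turn gave 2 to 41 genes in affected capsules, 0 to 1 in affected ligaments, 0 to 1850 in adult affected ligaments, 549 to 2203 between affected ligaments at 4 months and in adults, 617 to 1774 in young ligaments, and 0 to 715 for the age difference. All 30 genes of affected capsules and all 5 of the age difference kept their direction in each of these fits. The 30 had no overlap between the groups, so leaving out 1 library could hardly have reversed them. Leaving out 1 dog gave 252 to 497 genes between capsule and ligament.

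Replicate numbers did not pair the samples, since equal numbers belong to different dogs in each comparison of 2 groups, and in no comparison did every equally numbered pair of libraries deviate together (correlations -0.319 to 0.486). With the number as a replicate block, which also leaves out libraries without an equal number, counts were 6 in affected capsules (7 with control replicate 5 left out and no block), 204 in both affected ligament comparisons (which then hold the same 6 adult libraries) and 814 in young ligaments (848 with young replicate 4 left out and no block). Simulated 2-fold changes were recovered for 11 of 100 genes in affected capsules and 9 of 100 in affected ligaments, against 51 in young capsules and 61 within dog; depth was not separated from the number of libraries and their spread. Depth sets the floor of folds against groups without fragments, where 3 fragments over the group stood for 0.103 to 0.179 CPM.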

Other observations

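All tests in this part were chosen after the counts of calls had been seen. A score was made of the 30 genes called between affected and control capsules, as the mean log2 CPM of the 17 higher genes minus that of the 13 lower ones, and read in ligaments. No ligament library entered the choice of the genes, but 4 of the 10 ligaments came from dogs whose capsules did. Affected ligaments averaged -0.314 ± 1.42 (SD, n = 7) and control ligaments -2.76 ± 0.654 (n = 3), a difference of 2.44 (exact permutation p = 0.0417, adjusted over 4 tests 0.152), and the p was 0.0833 and 0.111 without control replicates 1 and 2. Among ligaments of other dogs alone, 4 affected averaged -0.63 and 2 controls -2.75, a difference of 2.12 (exact permutation p = 0.2). Ligaments of affected adults averaged -0.63 ± 1.42 (n = 4) and those of affected dogs aged 4 months 0.106 ± 1.59 (n = 3), which differed by less than the spread between libraries (exact permutation p = 0.571, adjusted 0.571). The 4 young ligaments stood at 1.41, 2.49, 2.79 and 2.93. ENSCAFG00000011534 averaged 296 ± 367 CPM in affected (n = 7) and 797 ± 356 CPM in young ligaments (n = 4), and 1090 ± 373 CPM in embryonic hip (n = 3). The 3 control ligaments stood at 17.7, 132.5 and 173.2 CPM, within the affected range, and the gene was not called between affected and control ligaments.

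The genes called between adult affected ligaments and controls without control replicate 3 went against the direction of youth in capsule. Of 1060 genes higher in adult affected ligaments, 237 (22.4%) had a positive fold change in young against control capsules. Of 765 lower genes, 214 (28%) had a negative one there. This shift did not pass with an estimated correlation (camera adjusted p = 0.34 and 0.53). The genes of this comparison showed little overlap with those of affected capsules, with 2 higher genes in both lists where 1.38 were expected and 1 lower gene where 0.746 was.

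The first principal component of all 32 libraries held 35.5% of the variance over 14345 genes, and the next held 13.6%. In 6 of the 7 dogs sampled for both tissues, the deviations of capsule and ligament from their group means correlated positively across genes, from 0.1 to 0.49, and in 1 dog aged 4 months the correlation was -0.227. The means of affected groups mix ages. Equally numbered libraries of different dogs gave correlations of -0.319 to 0.486, so an effect of the dog is not shown.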
